A study of Mus musculus with 9 samples.

How the data were processed

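Messenger RNA was measured in 9 libraries from ATDC5 cells, a mouse chondrogenic cell line that is used as a culture model of cartilage differentiation. The libraries formed 3 groups of 3, labelled control, acetate and ethanol. Per the labels' protocols, cells were grown in DMEM/F-12 with serum, and the medium was then enriched with ascorbate, beta-glycerophosphate and insulin-transferrin-selenium when the treatments were given. RNA was taken up in Trireagent and libraries were made with a stranded Illumina mRNA kit. The treatment protocol in the labels describes other material (mouse livers, and HepG2 cells given estradiol and cobalt chloride) and was not used here. The doses and times of acetate and ethanol were not given in the sources used here. Nothing in the labels says that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

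The authors deposited 1 table of log2 values for 26202 genes, which are TMM-normalised counts per the file name. Submitters' processing notes name Partek without a version, Bowtie2 2.2.5, STAR 2.7.8a and the build mm10, with no role or order. The annotation and the counting step were not given in the sources used here. Raised to a power of 2, each deposited column summed to the total expected of CPM divided by a factor of 0.936 to 1.04. This is what TMM scaling of CPM would give, so the log2 values lay on a TMM-scaled CPM scale. Genes without reads sat at a floor that differed between libraries, as an offset of 1e-05 read added before scaling would give. The floor of each library was subtracted, which gave TMM-scaled CPM, the unit of all levels below. From the same floor, library sizes of 28.7 to 41.9 M reads were recovered. Of the values between 1 and 20 recovered reads, 85.6% to 87.2% per library were whole within 0.02 read, so a part of the counting was fractional and the deposited log2 values were not treated as counts. A single read was worth 0.0231 to 0.0348 CPM.

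Genes with a mean of at least 1 CPM over the 9 libraries were tested, which left 12868. The log2 of the CPM value plus 1 was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and 1 variance per gene over all 9 libraries, 3 contrasts, moderated variances with a mean trend, and Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 are called past the threshold. Fold changes are on the scale of log2 of the value plus 1, which understates the change of genes with low levels. Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation. There were 42 lists, on cartilage and bone, growth factor signalling, metabolism, stress, inflammation, cell division and other cell types, of which 38 had at least 5 tested members. Lists could share members, such as Il6, Lif and Csf1 (NF-kB and osteoclast-regulating) and Sparc (fibrous matrix and osteoblast). Results of such lists are not independent findings. The groups, the test, the lists, the first set of alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per contrast, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups. It added up to 4 members past the threshold of each described list, and 9 genes in every case: Sox9, Col2a1, Acan, Col10a1, Runx2, Alpl, Acss2, Aldh2 and Adh5.

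Gene positions, transcript lengths and GC content came from GENCODE M21 on GRCm38, the same build as mm10. Of the genes in the table, 24919 matched by symbol, 445 through a synonym and 838 not at all. GC content was known for 12742 of the tested genes, 99.0%. Tables were handled in Python 3.11.15 with pandas 2.3.3 and drawn with matplotlib 3.10.9.

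The replicate numbers come from the labels, and whether they pair libraries was checked through correlations of the deviations from group means across genes. For ethanol against control, same-numbered libraries correlated at 0.55, 0.36 and 0.67, and for acetate against ethanol at 0.15, 0.25 and 0.61. Replicate number was therefore used as a block beside these contrasts, and for acetate against control in the same fit. The alternatives covered the pseudocount, the filter, the scaling, the variance model, library weights, the replicate block, the libraries in the fit and each library left out. Ranges of adjusted p over a gene's alternatives include the fit with library weights, whose estimation stopped before its tolerance was reached. The low ends of these ranges are therefore no measure of strength. A correction for GC content by lowess with a span of 0.3, voom on the recovered reads, and the block combined with the GC correction or with acetate replicate 2 left out were added after the data were seen.

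The procedure was tested on simulated data in which 200 genes were changed. A planted list of further genes was lowered as well and left out of the false calls. Reads were drawn independently per gene with the same dispersion in all libraries, without a GC trend, an outlying library or pairing. The false calls therefore do not measure the error rate in the real data. For acetate against control the procedure recovered 31.7%, 57.4% and 92.6% of genes changed 1.5, 2 and 4 times, over 12836 genes and with 3 false calls. For ethanol against control the shares were 31.0%, 72.2% and 92.9% with 17 false calls, and for acetate against ethanol 18.2%, 70.5% and 98.6% with 5.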

Results

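ATDC5 cells, which pass through the steps of cartilage differentiation in culture, were profiled by RNA sequencing as control, with acetate and with ethanol, in 3 libraries each. The labels do not say what the controls were given. Ethanol is oxidised to acetaldehyde and then to acetate, and the series asks whether acetate could carry part of the effect of ethanol on genes of chondrocyte differentiation and bone. The comparisons were acetate against control, ethanol against control, and acetate against ethanol directly. Levels are given as TMM-scaled CPM, mean ± SD with n = 3 libraries per group, from libraries of 28.7 to 41.9 M recovered reads. Errors of log2 fold changes are standard errors from limma, and adjusted p-values are from limma for genes and from camera for gene lists unless fry is named.

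Acetate replicate 2 stood apart from the other libraries. Against the mean of the other acetate libraries, 1622 genes differed by more than 2 times, 1588 of them lower. The difference followed the GC content of transcripts, with a Pearson r of 0.81 across 12742 genes, which are not independent replicates. Genes under 40% GC had a median of -1.50 on the log2 scale (753 genes) and genes of at least 55% GC a median of 0.45 (2818 genes). The log2 fold changes of acetate against control (r = 0.58 across genes) and of acetate against ethanol (r = 0.55) therefore carried a trend with GC content. That of ethanol against control did not to a similar extent (r = -0.06).

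**Figure D1:**
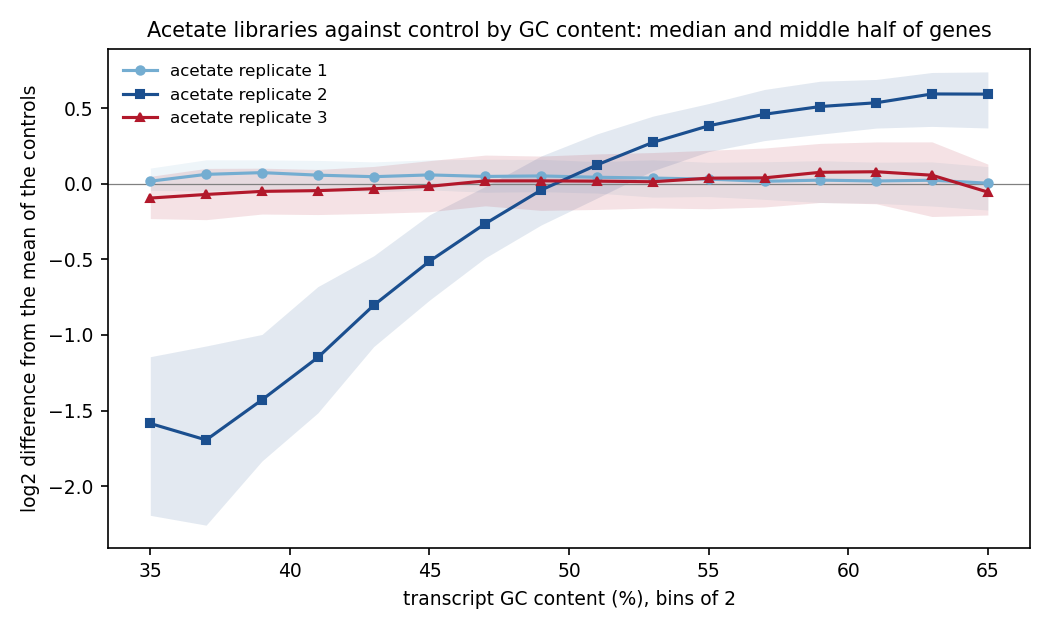
Log2 difference of each acetate library from the mean of the controls (vertical axis) against transcript GC content in bins of 2 percentage points (horizontal axis). Lines give the median and bands the middle 50% of genes; acetate replicate 2 runs from -1.59 at the lowest GC bin to 0.59 at the highest, and the other acetate libraries stay within 0.10 of 0.

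Acetate lowered the genes of the cartilage matrix. Of 20 tested cartilage matrix genes, 15 fell and none rose, with a median log2 fold change of -1.15. Col2a1, the main collagen of cartilage (chromosome 15, 97975602 to 98004695 on GRCm38), dropped from 9089 ± 1320 to 4346 ± 410 (log2 fold change -1.06 ± 0.15, adjusted p = 0.017). The chains of collagen IX, which sits on the surface of collagen II fibrils, fell further, with Col9a1 at 187 ± 28.3 in control and 52.1 ± 9.78 in acetate (-1.83 ± 0.19) and Col9a2 at -2.33 ± 0.26. Col10a1, the collagen of hypertrophic chondrocytes (chromosome 10, 34389981 to 34397085), went from 270 ± 26.5 to 81.6 ± 16.2 (-1.72 ± 0.15, adjusted p = 0.0042).

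Other cartilage genes that fell with acetate were the matrilin gene Matn4 (-2.01 ± 0.18), Snorc (-1.87 ± 0.20), Ucma (-1.71 ± 0.21), Col9a3 (-1.66 ± 0.18) and Clec3a, a cartilage-derived lectin (-2.56 ± 0.29). Acan, which codes for the proteoglycan aggrecan (chromosome 7, 79053483 to 79115099), stood at 1119 ± 233 in control and 588 ± 13.9 in acetate and missed the threshold (-0.91 ± 0.18, adjusted p = 0.055). Acan passed with replicate number as a block, with the GC trend removed (adjusted p = 0.0097) and without acetate replicate 2 (0.028, with 2.2e-31 to 0.26 over its alternatives). Another gene that missed the threshold was Sox9, the master regulator of chondrocytes (chromosome 11, 112782224 to 112787760), at 449 ± 42.6 and 301 ± 18.0 (-0.57 ± 0.12, adjusted p = 0.066). Sox9 passed with replicate number as a block, with the GC trend removed (0.0067) and without acetate replicate 2 (0.027, with 4.8e-12 to 0.30 over its alternatives). Among 21 chondrogenic regulators, 3 fell, namely Sox8 (-1.16), Sox5 (-0.55) and the growth factor gene Bmp6. Among 20 hypertrophic genes, 4 fell, namely Col10a1, Ihh, which codes for the hedgehog ligand of the growth plate (-0.97 ± 0.13), Mmp13 (-0.95) and Foxa3 (-0.94), of which only Col10a1 and Ihh passed with pseudocount 0.1 or with voom. Among 24 genes for the sugar chains of proteoglycans only Papss2, which makes the sulfate donor, fell past the threshold (-1.44 ± 0.19). Runx2 (-0.15, adjusted p = 0.54) and Alpl (0.12, adjusted p = 0.61), genes of mineralising cells, did not pass.

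The largest rises with acetate were those of the laminin gene Lama5, from 24.5 ± 2.04 to 66.6 ± 18.9 (1.38 ± 0.18, adjusted p = 0.016), the transcription factor gene Foxs1 (1.26 ± 0.20), the immediate early gene Arc (1.21 ± 0.20) and Hmga1, a chromatin protein gene (1.21 ± 0.12). Hmga1b rose as well, but it is a near-identical copy of Hmga1 and the reads of both may have been split. Aqp5, Kif1a, Zfpm1, Crybb1 and Fbln1 rose by 1.03 to 1.18. Csf1, the macrophage and osteoclast growth factor gene, rose from 91.4 ± 2.88 to 179 ± 32.7 (0.94 ± 0.14). Of 27 interferon response genes 2 rose, Mx2 (0.95) and Cxcl10 (0.92), and the list had a median of 0.38. Without acetate replicate 2 its median was 0.25 and 4 genes rose, 1 rose with pseudocount 0.1 or voom, and neither passed with median-of-ratios scaling. Mx2 is annotated as a polymorphic pseudogene.

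Across 12868 genes, limma placed 129 past the threshold for acetate, 65 higher and 64 lower, 54 of them by at least 2 times, and 1875 had an unadjusted p under 0.05. With replicate number as a block it placed 293, of which 175 were higher and 118 lower, and 128 were shared. In all 129 the 3 acetate values lay on one side of the 3 control values; over all genes 19.5% were so separated, where chance gives 10%. Adjusted over the list alone, 19 cartilage matrix genes fell, as did 7 chondrogenic regulators, 6 hypertrophic genes and 5 sugar-chain genes, while 3 regulators, 1 hypertrophic gene and 8 interferon response genes rose. The cartilage matrix list was lower as a whole in camera (adjusted p = 2.1e-25, but adjusted p = 0.13 with an estimated correlation). The lists of chondrogenic regulators (adjusted p = 0.017), hypertrophic genes (0.010) and sugar-chain genes (0.0072) were lower, and interferon response genes higher (5.2e-08), each with adjusted p = 0.46 with an estimated correlation. In fry the adjusted p was 0.0016 for cartilage matrix and 0.040 for sugar-chain genes. Fry gave 0.057 for chondrogenic regulators, 0.059 for hypertrophic and 0.087 for interferon response genes. With the GC trend of each library removed, Sox5 had adjusted p = 0.11 (7.2e-09 to 0.23 over its alternatives) and Mmp13 0.079 (4.8e-07 to 0.16). Single libraries decided the number of calls: limma gave 0 genes without control replicate 3 (1720 at an unadjusted p under 0.05), 3 without control replicate 1, 27 without control replicate 2, 33 without acetate replicate 3, 56, 54 and 52 without ethanol replicate 1, 2 and 3, and 448 without acetate replicate 2. The near-even split of higher and lower genes was not stable: 4 rose and 23 fell without control replicate 2, 0 and 3 without control replicate 1, 11 and 22 without acetate replicate 3, 17 and 39, 17 and 37, and 16 and 36 without ethanol replicate 1, 2 and 3, and 3 and 17 with only the 6 libraries compared, against 251 and 197 without acetate replicate 2. Of 37 genes named by the rule, 37 kept their call without acetate replicate 2, 2 without control replicate 1 and 0 without control replicate 3. Without acetate replicate 2, 5 chondrogenic regulators (median -0.08) and 5 sugar-chain genes fell, and the hypertrophic list had a median of -0.03.

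**Figure D2:**
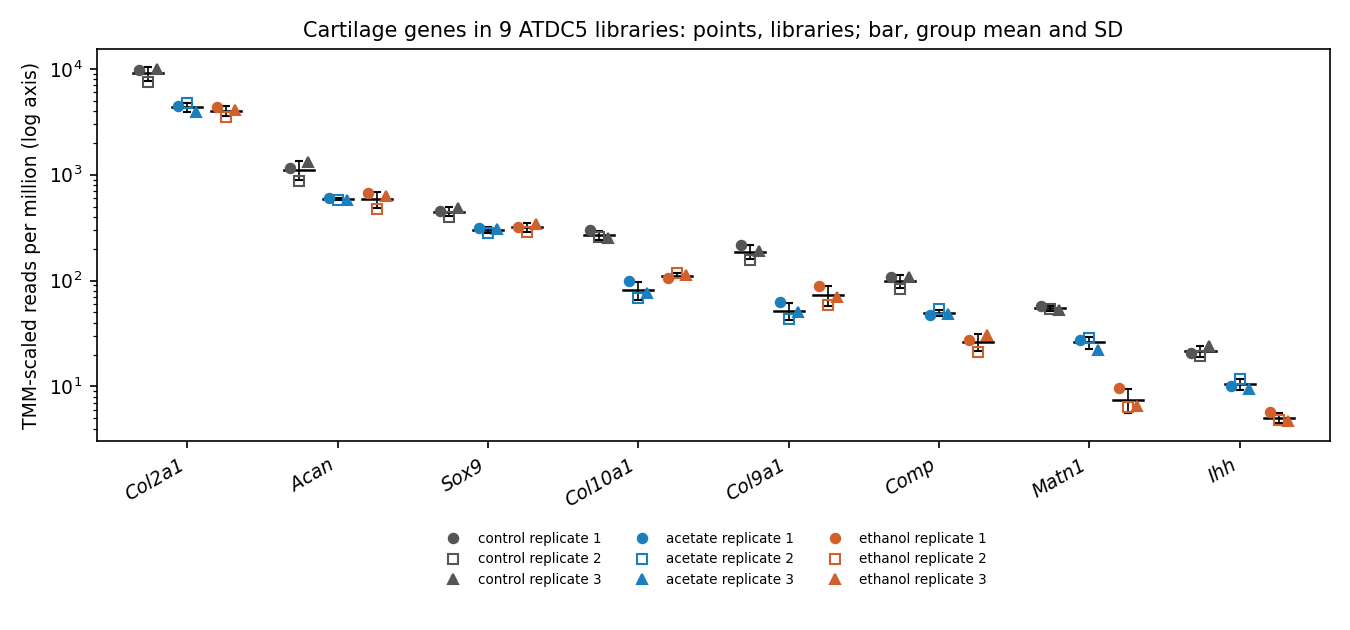
TMM-scaled CPM (log axis) of 8 cartilage genes in each of the 9 libraries; points are libraries, horizontal bars group means and whiskers SD (n = 3). For Col2a1 the control mean was 9089 against 4346 in acetate and 4008 in ethanol, and Matn1 and Ihh were lowest in ethanol, at 7.51 and 5.05.

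Ethanol lowered the cartilage matrix to a similar median (-1.21), with 16 of the 20 genes past the threshold and none higher. Col2a1 dropped to 4008 ± 447 (-1.18 ± 0.15, adjusted p = 0.0048), Acan to 589 ± 100 (-0.92 ± 0.18, adjusted p = 0.027) and Col10a1 to 111 ± 6.15 (-1.27 ± 0.15, adjusted p = 0.0037). Matn1, a matrilin gene of growth plate cartilage (chromosome 4, 130944385 to 130955475), had the deepest fall of the group, from 54.7 ± 2.72 to 7.51 ± 1.88 (-2.73 ± 0.17, adjusted p = 3.9e-04). Snorc (-2.12 ± 0.20), Col9a2 (-1.93 ± 0.26) and Comp, which codes for a pentameric matrix protein (-1.88 ± 0.16), followed. Interferon response genes went the other way: 16 of 27 rose and none fell.

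Of the 20 hypertrophic genes 6 fell with ethanol, led by Ihh from 21.4 ± 2.42 to 5.05 ± 0.567 (-1.89 ± 0.13, adjusted p = 5.4e-04), Foxa2 (-1.31) and Col10a1. Sox9 stood at 317 ± 29.7 (-0.50 ± 0.12) and missed the threshold (adjusted p = 0.056), which it passed with replicate number as a block (adjusted p = 0.022; 4.1e-12 to 0.26 over its alternatives). Genes of the fibrous matrix fell too, 5 of 25 with 1 rise, among them the small proteoglycan genes Lum, from 190 ± 48.6 to 27.8 ± 9.83 (-2.75 ± 0.37, adjusted p = 0.0054), and Dcn (-1.76 ± 0.25), and the crosslinking enzyme gene Loxl2 (-1.06). Among 19 osteoblast and mineralisation genes 4 fell: Bglap, which codes for osteocalcin (-1.65 ± 0.19), its near-identical neighbour Bglap2 (-1.45), with which reads may have been shared, Alpl from 819 ± 66.3 to 540 ± 9.82 (-0.60 ± 0.13, adjusted p = 0.039; 7.6e-15 to 0.19 over its alternatives) and Sparc (-0.57 ± 0.11, adjusted p = 0.030; 1.8e-07 to 0.80). The calls of Alpl and Sparc were each lost without any 1 control or ethanol library, and with quantile scaling Sparc turned to 0.05. Alpl is also counted in the hypertrophic list and Sparc in the fibrous matrix list. Runx2 did not pass (-0.16, adjusted p = 0.56).

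All 27 genes of the glycolysis and hypoxia list had negative fold changes with ethanol, and 6 passed the threshold. They included Car9, a carbonic anhydrase gene induced by low oxygen (35.1 ± 9.20 to 10.3 ± 2.86, -1.67 ± 0.31), the oxygen sensor gene Egln3 (-1.28 ± 0.20) and P4ha1 and P4ha2, which code for collagen prolyl hydroxylases (-1.06 ± 0.15 and -1.04 ± 0.16). The lactate exporter gene Slc16a3 fell from 32.4 ± 5.05 to 12.3 ± 2.00 (-1.33 ± 0.17, adjusted p = 0.0045). Outside the lists, Ndufa4l2 (-2.21 ± 0.34), Syt8 (-2.11), F13a1, a transglutaminase gene (-2.06 ± 0.14), Slpi (-1.99), Rtl3 (-1.95) and Sema3b (-1.91) were among the largest falls.

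The largest rises with ethanol included Apobr, an apolipoprotein receptor gene (1.74 ± 0.22), and several antiviral genes. Rsad2, which codes for viperin (chromosome 12, 26442746 to 26456452), rose from 80.3 ± 12.4 to 265 ± 14.2 (1.72 ± 0.13, adjusted p = 6.9e-04) and Ifit1 from 130 ± 16.2 to 351 ± 18.2 (1.43 ± 0.13, adjusted p = 0.0012). Cxcl10 (1.30 ± 0.17), Mx1 (1.33 ± 0.20), Zbp1 (1.58 ± 0.34) and Ifit1bl2 (1.54 ± 0.20) rose as well, and reads of Ifit1bl2 can be shared with related Ifit genes. Among 18 NF-kB and inflammation genes 6 rose, including the chemokine genes Ccl2 (3.99 ± 0.264 to 10.7 ± 0.672, 1.23 ± 0.12), Ccl7 (1.12) and Cxcl1 (1.03), and the cytokine gene Il6 (2.24 ± 0.202 to 6.71 ± 0.119, 1.25 ± 0.25, adjusted p = 0.030). Among 25 immediate early genes 3 rose, including Egr1 (1.59 ± 0.36) and Ier2 (0.93), and 7 rose and 2 fell with replicate number as a block. Hap1 rose by 1.36 ± 0.28.

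**Figure D3:**
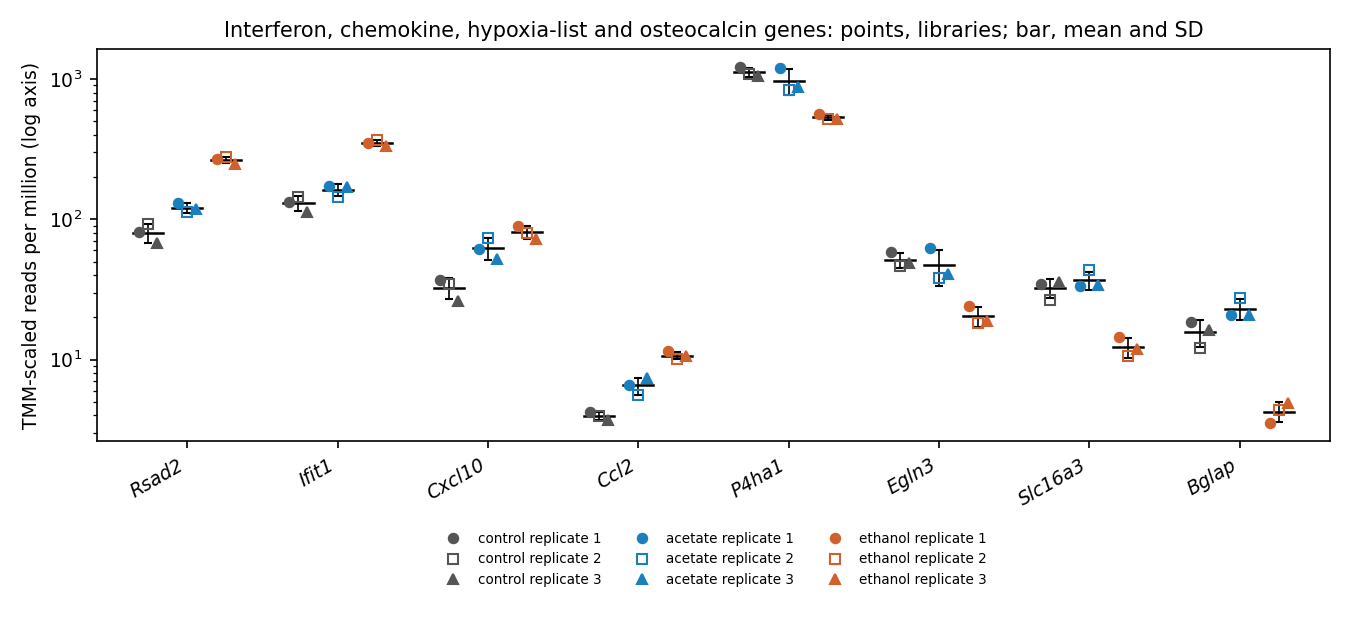
TMM-scaled CPM (log axis) of 8 genes in each of the 9 libraries; points are libraries, horizontal bars group means and whiskers SD (n = 3). The ethanol libraries lie above the others for Rsad2 (mean 265 against 80.3 in control and 121 in acetate) and below them for Slc16a3 (12.3 against 32.4 and 36.8).

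For ethanol, limma placed 506 genes past the threshold, 191 higher and 315 lower, 152 of them by at least 2 times, and 1074 with replicate number as a block, 503 of them shared. The split was more even with the GC trend removed, at 984 higher and 1066 lower, and at 1309 and 1457 without acetate replicate 2. All 506 had 3 ethanol values on one side of the 3 control values, as had 43.4% of all genes, where chance gives 10%. Adjusted over the list alone, 18 cartilage matrix, 7 hypertrophic, 18 fibrous matrix, 9 osteoblast and 16 glycolysis and hypoxia genes fell, and 20 interferon response, 11 NF-kB and 9 immediate early genes rose. In the opposite direction the same adjustment gave 1 hypertrophic, 1 fibrous matrix and 3 osteoblast genes higher, and 1 NF-kB and 3 immediate early genes lower. With the block, 10 fibrous matrix, 7 osteoblast and 12 glycolysis and hypoxia genes fell, and 1 fibrous matrix and 2 osteoblast genes rose. Without acetate replicate 2, 18 fibrous matrix, 11 osteoblast and 18 glycolysis and hypoxia genes fell and 12 NF-kB and 12 immediate early genes rose, with 1 fibrous matrix and 2 osteoblast genes higher and 1 NF-kB and 3 immediate early genes lower. In camera the NF-kB list was higher (adjusted p = 4.2e-08) and stayed so with an estimated correlation (adjusted p = 0.029), the only list of 38 that did. Its estimated correlation was -0.026, below the preset 0.01, against 0.40 for cartilage matrix and 0.55 for interferon response. The lists were thus not penalised alike, and these estimates came from all 9 libraries, acetate replicate 2 included. Cartilage matrix had adjusted p = 4.0e-22, but adjusted p = 0.18 with an estimated correlation. The hypertrophic (2.9e-06), fibrous matrix (2.9e-09), glycolysis and hypoxia (7.4e-13) and interferon response lists (5.5e-20) each had adjusted p = 0.22 with an estimated correlation. For the osteoblast list adjusted p = 2.5e-04 became adjusted p = 0.33 with an estimated correlation, and for immediate early genes 0.0044 became 0.38. In fry the adjusted p was 0.0014 for cartilage matrix, 0.0033 for fibrous matrix and 0.013 for glycolysis and hypoxia. Fry gave 0.0058 for the hypertrophic and interferon response lists, 0.018 for osteoblast, 3.0e-05 for NF-kB and 0.088 for immediate early genes. Another division of the same 6 libraries gave 19 lists past the threshold at the preset correlation, against 16 for the true one, so the number of list calls did not set the true division apart. Every other division puts libraries of both groups on each side. It thus keeps part of any treatment difference and is no measure of chance alone. Limma gave 98, 200 and 182 genes without control replicate 1, 2 and 3, 217, 109 and 160 without ethanol replicate 1, 2 and 3, and 2766 without acetate replicate 2, and of the 70 genes named by the rule 33, 44 and 39, 46, 35 and 42, and 70 kept their call. Acetate replicate 2 entered the spread of every gene, and with only the 6 libraries compared limma gave 3443 genes. The number 506 and the genes that missed the threshold with ethanol thus depend on that shared spread.

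The direct comparison of acetate with ethanol asks where the treatments differ, and genes of bone, fibrous matrix, hypoxia and cartilage were among those that passed. Bglap was 23.1 ± 3.97 in acetate and 4.26 ± 0.692 in ethanol (2.19 ± 0.19, adjusted p = 0.0011), and 7 of 19 osteoblast genes were higher in acetate with none lower, including Bglap2 (2.24), Ifitm5 (0.84) and Alpl (0.72 ± 0.13, adjusted p = 0.017). Of 27 glycolysis and hypoxia genes 6 were higher in acetate, with Slc16a3 outside that list at 1.51 ± 0.17, Car9 at 1.51 ± 0.31 and Egln3 at 1.14 ± 0.20. Of 25 fibrous matrix genes 5 were higher and 1 lower, with Lum at 1.82 ± 0.37, Fbln1 at 1.25 ± 0.18 and Fbln2 at 1.22 ± 0.13. Interferon response genes were lower in acetate for 4 of 27, with Rsad2 at -1.13 ± 0.13 and Ifit1 at -1.11 ± 0.13. In camera the osteoblast (adjusted p = 3.1e-04), fibrous matrix (1.8e-05), glycolysis and hypoxia (1.1e-06) and interferon lists (1.6e-06) differed, each with adjusted p = 0.67 with an estimated correlation, and cartilage matrix did not (adjusted p = 0.62). In fry the adjusted p was 0.027 for osteoblast and 0.019 for fibrous matrix. Fry gave 0.070 for glycolysis and hypoxia, 0.094 for interferon response and 0.88 for cartilage matrix. No test compared the lists with each other.

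Of 20 cartilage matrix genes 4 passed this test, 3 higher and 1 lower in acetate. Col2a1 (0.12 ± 0.15, adjusted p = 0.63), Acan (0.01 ± 0.18, adjusted p = 0.97) and Sox9 (-0.07 ± 0.12, adjusted p = 0.71) did not pass, nor did Col10a1 (-0.46 ± 0.15, adjusted p = 0.14), which passed with the GC trend removed (0.039; 7.7e-05 to 0.37 over its alternatives). Matn1 (1.68 ± 0.17, adjusted p = 0.0015), Comp (0.91 ± 0.16) and Chad (0.68) were higher in acetate, as was Ihh (0.92 ± 0.13, adjusted p = 0.0080), and Col9a3 was lower (-0.88 ± 0.18). Chondrogenic transcription factor genes Sox8 (-0.73), Sox4 (-0.66) and Sox5 (-0.57) were lower in acetate, and Sox5 had adjusted p = 0.063 with the GC trend removed (6.5e-10 to 0.084 over its alternatives). These were 3 of 21 chondrogenic regulators, of which 8 had positive and 13 negative changes. Camera did not call that list (adjusted p = 0.39). Beside Bglap2, Bglap and Lum, given above, the largest differences in favour of acetate were Ndufa4l2 (2.44 ± 0.34), Hspb7, a small heat shock protein gene (170 ± 33.4 against 33.0 ± 3.59, 2.32 ± 0.16), Ecrg4 (2.18), Lama5 (2.16), Col24a1 (1.93), F13a1 (1.84) and Sema3b (1.77). In favour of ethanol they were the cold-induced RNA-binding protein gene Rbm3 (225 ± 86.8 against 690 ± 29.3, -1.70 ± 0.27), the guanylate-binding protein gene Gbp2b (-1.42), Gjc3 (-1.33), Galnt13 (-1.30), Ecm2 (-1.23) and Nmi (-1.16).

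Among genes that handle ethanol and acetate themselves, the lactate and monocarboxylate exporter gene Slc16a3 fell with ethanol (-1.33 ± 0.17) and differed between the treatments (1.51 ± 0.17). Acss2, which activates acetate to acetyl-CoA (chromosome 2, 155517948 to 155585724), was 28.8 ± 3.17 in control, 25.1 ± 6.48 in acetate and 17.5 ± 2.95 in ethanol, and did not pass for acetate (-0.22 ± 0.20, adjusted p = 0.56) or ethanol (-0.69 ± 0.20, adjusted p = 0.10), though for ethanol it passed with the block (adjusted p = 0.028), without acetate replicate 2 (0.023) and with the GC trend removed (0.048; 5.5e-18 to 0.38 over its alternatives). Aldh2, the mitochondrial acetaldehyde dehydrogenase gene, did not pass in either (0.11, adjusted p = 0.78, and -0.46, adjusted p = 0.30), though for ethanol it passed without acetate replicate 2 (0.042; 5.4e-11 to 0.71 over its alternatives). Adh5 did not pass (-0.04, adjusted p = 0.87, and -0.08, adjusted p = 0.80). Of 11 tested genes of ethanol and aldehyde oxidation, Aldh1a3 fell with acetate (-0.75), the 1 gene past the threshold adjusted over the list alone too, and limma called 0 with ethanol. Of 10 genes of acetate transport and use, 1 fell with ethanol and 3 fell adjusted over the list alone, and that list was lower in camera (adjusted p = 0.040, but adjusted p = 0.38 with an estimated correlation), a call lost without acetate replicate 2 (0.076). Of 29 protein acetylation enzyme genes, Hdac11, a deacetylase gene, fell with ethanol (-0.94).

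Between acetate and ethanol, limma placed 480 genes past the threshold, 366 higher and 114 lower in acetate (76% of them higher), and 823 with replicate number as a block, 475 of them shared. The split was more even with the GC trend removed, at 825 higher and 615 lower, and at 736 and 372 without acetate replicate 2. All 480 were without overlap between the groups, as were 27.8% of all genes, where chance gives 10%. Adjusted over the list alone, 8 osteoblast, 9 fibrous matrix and 15 glycolysis and hypoxia genes were higher in acetate and 12 interferon response genes lower, with 1 osteoblast and 1 fibrous matrix gene going the other way. With the block, 8 fibrous matrix genes were higher and 9 interferon response genes lower, and without acetate replicate 2 the latter were 12. The count was 281 and 315 without control replicate 1 and 2, 179, 103 and 161 without ethanol replicate 1, 2 and 3, and 1108 without acetate replicate 2, and of the 67 genes named by the rule 46 and 50, 28, 25 and 29, and 66 kept their call. With the GC trend removed, 61 of the 67 kept it. With only the 6 libraries compared, limma gave 107 genes.

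**Figure D4:**
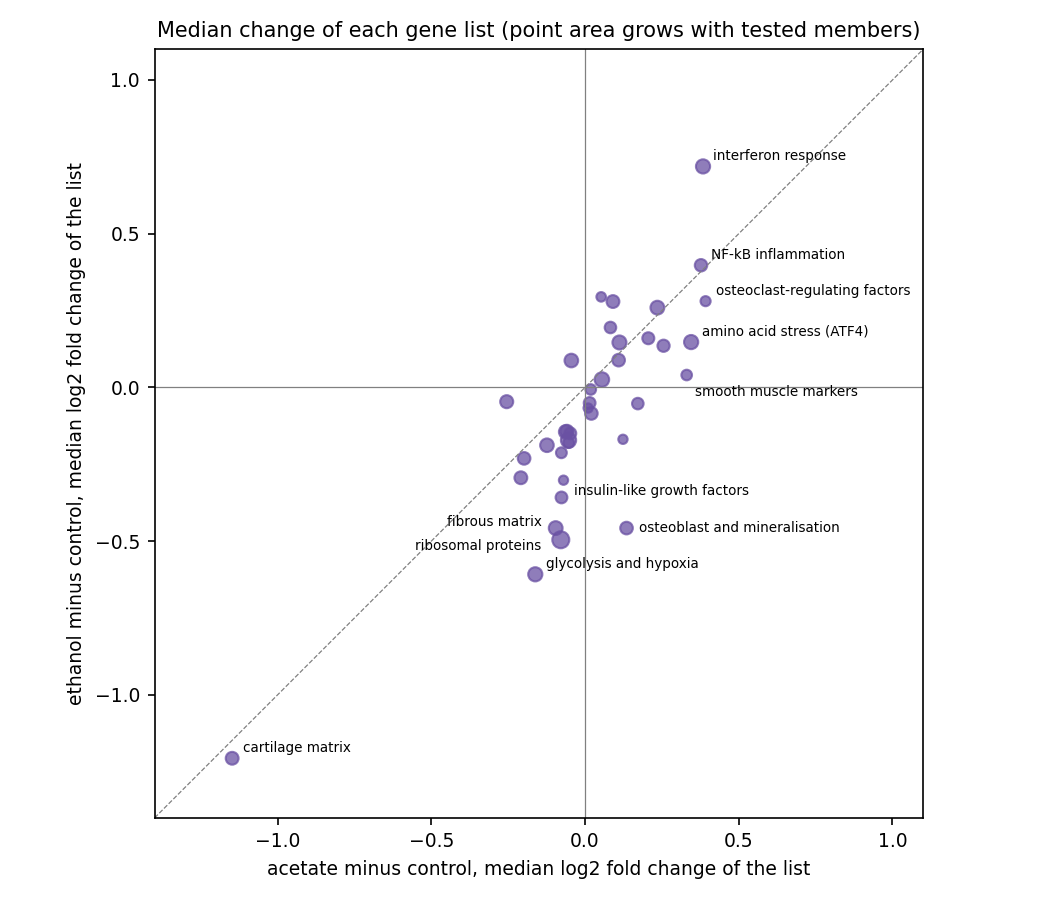
Median log2 fold change of each gene list with at least 5 tested members after acetate (horizontal axis) and ethanol (vertical axis), each against control; point area grows with the number of tested members and the dashed line marks equal change. The cartilage matrix list sits near the line at -1.15 and -1.21, and the glycolysis and hypoxia list below it at -0.16 and -0.61.

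The changes of the treatments against the same controls overlapped. Of the 64 genes lowered by acetate and the 315 lowered by ethanol, 47 were shared, where independent lists would share 1.57, and of the 65 and 191 higher genes 15 were shared, against 0.965. Another 5 genes passed in opposite directions, such as Lama5, which fell with ethanol (-0.79 ± 0.18, adjusted p = 0.046). Of the 315 genes lowered by ethanol, 150 also differed between acetate and ethanol in the direct test, as did 13 of the 64 lowered by acetate, 55 of the 191 raised by ethanol and 37 of the 65 raised by acetate. The log2 fold changes correlated at r = 0.33 across genes, and unchanged groups simulated against shared controls gave 0.24 (0.22 to 0.27 in 100 simulations) and shared 0 calls. Each gene and library was drawn independently, without the correlation among genes or between same-numbered libraries seen here. The simulated ranges are therefore too narrow, and 0 shared calls was the only likely outcome. No excess over the simulation was tested. The covariance was 0.0362 against 0.00767 simulated, a difference of 0.0285. Changes of the same sign made up 59.7% of genes, against 60.7% simulated. Without acetate replicate 2 the correlation was 0.53 against 0.39 simulated, the covariance 0.0403 against 0.00767, the share of the same sign 69.8% against 65.3%, and 154 lower and 105 higher genes were shared, where independent lists would share 22.3 and 25.5. Without acetate replicate 3 the correlation was 0.18 against 0.17 simulated (0.15 to 0.19), no higher than the simulation gave. The share of the same sign was 53.1% against 59.9%, the covariance 0.0241 against 0.00769, and 16 lower and 1 higher genes were shared. Without acetate replicate 1 the correlation was 0.31 against 0.18 simulated and the covariance 0.0441 against 0.00770. Without replicate 3, acetate replicate 2 makes up more of the acetate mean, so the lower correlation was not separated from that library. With 3 controls no split into separate control sets of 2 was possible. Part of any excess may thus come from the shared controls, or from the correlations that the simulation left out.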

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

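The GC correction, voom, the combinations with the block other than the block alone, the counts of list members and quantile scaling for named genes were chosen after the data were seen. No count of calls reversed, and 1 named gene did: Sparc with ethanol went from -0.57 to 0.0536 with quantile scaling. For named genes, 2125 values under an alternative stayed on the same side of the threshold in the same direction, 616 were weaker and 16 stronger. The pseudocounts, the values as deposited, no filter, median-of-ratios and quantile scaling, no variance trend, the robust fit and voom moved no count over all genes by over 1.5 times, though among list members the hypertrophic genes lower with acetate went from 4 to 2 with pseudocount 0.1 and voom; quantile scaling changed the acetate split from 65 higher and 64 lower to 38 and 62. Counts below are for acetate against control, ethanol against control, acetate against ethanol and the F test over the 3 groups, in that order, from 129, 506, 480 and 671. They were 29, 220, 222 and 275 for genes with a mean of at least 10 CPM, 293, 1074, 823 and 1242 with the replicate block, 661, 2050, 1440 and 2370 with the GC trend removed, 2283, 4624, 3922 and 5606 with both, and 2773, 6466, 4262 and 7179 with the block and acetate replicate 2 left out. Library weights (arrayWeights) gave 5016, 6964, 3700 and 8418, from an estimation that stopped before its tolerance was reached, with a weight of 0.0442 for acetate replicate 2. Fits of only the 6 libraries compared gave 20, 3443 and 107, and an absolute log2 fold change of at least 1 left 54, 152 and 136. Leaving out 1 library gave 0 (control replicate 3, with 1720 at an unadjusted p under 0.05 in limma) to 448 (acetate replicate 2), 98 (control replicate 1) to 2766 (acetate replicate 2), 103 (ethanol replicate 2) to 1108 (acetate replicate 2) and 150 (ethanol replicate 2) to 2470 (acetate replicate 2). Each gene had 1 spread over all 9 libraries, so acetate replicate 2 entered the error of every contrast, also of ethanol against control. Its deviation within its group had an SD of 0.68, against 0.13 to 0.22 in the control and ethanol libraries. Ethanol against control rose from 506 to 2766 without it and to 3443 with only its own 6 libraries. Acetate against control went the other way, from 129 to 20 with only the 6 libraries compared, and acetate against ethanol from 480 to 107. The shared spread may therefore understate the error of contrasts with acetate, though these fits also hold fewer libraries. Beyond the spread and GC trend of acetate replicate 2 no cause was tested. All 129 and 506 calls against control and 478 of the 480 were kept without it, and 125, 489 and 448 with the GC trend removed. With an estimated correlation, camera called 0, 1 and 0 lists (3, 8 and 1 at an unadjusted p under 0.05), from 12, 16 and 10; leaving out 1 library gave 10 to 19 lists (acetate replicate 2) for acetate against control. The correlation between the treatments' changes was 0.46 with the GC trend removed, with or without the block, 0.53 with the block and acetate replicate 2 left out, and 0.18 (without acetate replicate 3) to 0.53 (without acetate replicate 2) with 1 library left out. For acetate against control same-numbered libraries correlated at 0.25, -0.10 and 0.41. Deviations within acetate followed GC content (r = -0.77, 0.81 and -0.62 for replicates 1, 2 and 3), so pairing could not be judged there. Over all groups, 8 of 9 libraries matched best with their own number in another group. Beyond the calls given with the block, it raised the osteoclast-regulating list for ethanol to adjusted p = 0.063 and the amino acid stress list to 0.053 in camera. With the block Acan (adjusted p = 0.025) and Sox9 (0.029) passed for acetate. At the depth of these libraries 1 read was worth 0.0231 to 0.0348 CPM.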

Other observations

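The tests of depth, of GC content for ethanol, of a control or ethanol library under a wrong label and of a shift in 1 replicate number, the reading of the 3 blood markers, and the divisions that hold each replicate number once per group were chosen after the result was seen. With ethanol, all 44 ribosomal protein genes had negative fold changes (median -0.50); limma called 0 of them, and 21 fell with replicate number as a block or 12 without acetate replicate 2 (camera adjusted p = 6.2e-11, but adjusted p = 0.38 with an estimated correlation). Endoplasmic reticulum chaperone genes fell for 3 of 19, Sdf2l1 (-0.68), Pdia4 (-0.63) and Calr (-0.55), or for 10 without acetate replicate 2, with a list adjusted p = 2.5e-04 that became adjusted p = 0.22 with an estimated correlation. Hedgehog pathway genes Ptch1 (290 ± 29.6 to 152 ± 13.0, -0.93 ± 0.13) and Gli1 (-0.82 ± 0.15), both targets of the pathway, fell with ethanol, and Ptch1 fell with acetate (-0.76 ± 0.13), though the list of 10 was not called by camera (adjusted p = 0.088 and 0.50). Insulin-like growth factor genes fell for 2 of 15 with ethanol, Igfbp7 (-0.97 ± 0.10) and Igfbp2 (-0.95 ± 0.18), and for 6 with the block or 8 without acetate replicate 2 (camera adjusted p = 2.5e-04, but adjusted p = 0.22 with an estimated correlation). The Wnt inhibitor gene Dkk1 fell with ethanol (to 4.29 ± 1.26) and the BMP inhibitor gene Nog fell too (-0.80).

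With acetate, smooth muscle and myofibroblast markers were higher for 2 of 10, Tpm2 (72.5 ± 4.05 to 124 ± 20.5, 0.75 ± 0.13) and Synpo2 (0.73), with camera adjusted p = 2.2e-04, but adjusted p = 0.46 with an estimated correlation. Amino acid stress genes, targets of ATF4, had positive fold changes for 26 of 27 with acetate (median 0.35); limma called 0 of them over all genes, 3 without acetate replicate 2 and 15 adjusted over the list alone, with camera adjusted p = 1.4e-08, but adjusted p = 0.46 with an estimated correlation. Osteoclast-regulating factors were higher in camera with acetate (adjusted p = 0.011, but adjusted p = 0.27 with an estimated correlation), where Csf1 rose, or 5 genes without acetate replicate 2, and with ethanol 3 of 8 rose, Il6, Lif (0.81) and Csf1 (0.59). All 3 are also members of the NF-kB list and were counted there too. Plin4, a lipid droplet protein gene on the adipocyte list, fell with acetate (-1.16 ± 0.12) and ethanol (-1.60 ± 0.12). Some lists passed in camera with few or no single genes past the threshold. Wnt targets were higher with acetate (adjusted p = 0.026) and endoplasmic reticulum chaperones lower (0.031), each with adjusted p = 0.46 with an estimated correlation, and DNA replication genes were higher with ethanol (0.010, but adjusted p = 0.33 with an estimated correlation), where Tyms rose (0.49). Between acetate and ethanol, ribosomal protein genes (43 of 44 positive, camera adjusted p = 7.5e-06), insulin-like growth factor genes (1.8e-05), smooth muscle markers (0.0029), ATF4 targets (0.0033), fatty acid oxidation genes (0.040) and BMP targets (0.044) were higher in acetate, each with adjusted p = 0.67 with an estimated correlation; without acetate replicate 2 the ATF4 (0.14) and BMP (0.054) calls were lost. With acetate the NF-kB list (adjusted p = 2.2e-04, but adjusted p = 0.13 with an estimated correlation) and immediate early genes (5.8e-04, but adjusted p = 0.46 with an estimated correlation) were higher too. With ethanol, osteoclast-regulating factors (0.049, but adjusted p = 0.22 with an estimated correlation) and ATF4 targets (0.037, but adjusted p = 0.54 with an estimated correlation) were higher, calls lost with the block at 0.063 and 0.053, and oxidative phosphorylation genes were lower (0.013, but adjusted p = 0.56 with an estimated correlation). In the lists for sterol synthesis, fatty acid synthesis, heat shock, mitosis and oxidative phosphorylation limma called 0 genes in any comparison with all 9 libraries and no block. Adjusted over the list alone, 1 heat shock gene was higher in acetate than in ethanol. Without acetate replicate 2 ethanol lowered 4 fatty acid synthesis, 2 sterol synthesis and 2 heat shock genes and raised 1 mitosis gene, and 1 sterol synthesis and 1 heat shock gene were higher in acetate than in ethanol. With the block ethanol lowered 2 oxidative phosphorylation genes and 1 fatty acid synthesis gene, and 2 heat shock genes and 1 fatty acid synthesis gene were higher in acetate than in ethanol.

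Acetate replicate 2 differed from the other acetate libraries with a strong relation to GC content (r = 0.808), and removing each library's GC trend left 29.1% of the variance of its deviation. It did not have the fewest reads (rank 2 from the lowest of 9), which argues against depth. No marker list of another cell type with at least 5 tested members had a median deviation above 0.223 (smooth muscle). Markers present in that library alone could miss the filter of 1 CPM on the mean over 9 libraries. Blood, skeletal muscle and hepatocyte lists had only 3, 2 and 1 tested members, and the deviations carried the GC trend. The test therefore cannot decide on cells of another type. The deviations of acetate replicate 2 from the control mean (r = 0.768) and from the ethanol mean (r = 0.757) followed GC content too, which argues against a control or ethanol library under a wrong label as the whole cause. Over 146 genes that set the other acetate libraries apart from control and ethanol, it lay nearest to the acetate mean at 76.0% (85.9% of 142 with the GC trend removed), and the first value lies between the bounds written for a wrong label and against one, so a wrong label beside the GC trend, or a sample from outside, cannot be told apart. A candidate explanation is a bias with GC content in library preparation or sequencing, and no biological explanation was tested.

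Interferon response genes were higher after ethanol in each replicate number, by a median of 0.656, 0.728 and 0.854, the smallest 76.8% of the largest. Members past the threshold had no overlap between groups, which fixed their rise in every number. The 11 members that did not pass had medians of 0.482, 0.574 and 0.696, which argues against a shift in 1 number as the whole cause. Other genes within 1 point of the members' GC percent changed by 0.102% of the list's median change, and over all genes the ethanol changes correlated with GC content at only r = -0.0578, which argues against GC content. The tested macrophage and blood markers had a median of -0.578, with Lyz2 at -0.58, Cd14 at -0.01 and Laptm5 at -1.19, which argues against added blood cells as far as 3 markers can. A response of the cells to ethanol may underlie the pattern, as a hypothesis found and tested on the same data.

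Cartilage matrix genes were lower in each treated library than in the control with the same number. The medians were -1.17, -0.98 and -1.28 for acetate and -1.17, -1.13 and -1.22 for ethanol, the smallest at least 76.6% of the largest. Members past the threshold had no overlap between groups, which fixed their fall in every number. The 5 members that did not pass for acetate had medians of -0.477, -0.515 and -0.989, and the 4 for ethanol -0.185, -0.462 and -0.682. These fell in every number too, but less evenly, so the test does not decide on a shift in 1 number. The whole list kept 105.294% of its median change for acetate with the GC trends removed, and with ethanol other genes within 1 point of the members' GC percent changed by 1.196% of the list's median change, which argues against GC content. Fewer cartilage cells among other cells cannot be told apart from lower expression: the medians of smooth muscle, fibrous matrix and osteoblast lists lay up to 0.498 apart (0.04, -0.46 and -0.46 for ethanol; 0.33, -0.10 and 0.14 for acetate), between the bounds written for and against it. The fibrous matrix and osteoblast lists share Col1a1, Col1a2 and Sparc, and their ethanol medians were the same value, -0.457494. A shared gene can be the median of both, so the gap did not compare separate lists. A lower state of chondrocyte differentiation with either treatment may be the biological reading, and it stays open beside fewer cartilage cells.

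Other divisions of the libraries were run for each count. Each comparison has 10 divisions of its 6 libraries, too few for a share under 0.05. The true division gave 129, 506 and 480 genes in limma and ranked 1 of 10 each time, and the highest of the others gave 0 (at most 2069, 444 and 1211 genes at an unadjusted p under 0.05, against 1875, 2444 and 2709 for the true one, so for acetate against control another division gave more). For lists the true values of 12, 16 and 10 stood against a highest other of 9, 19 and 12, and 1, 4 and 2 of the 10 divisions were as large, the true one included. Every other division of 6 libraries puts both groups on each side and keeps part of any treatment difference. These list counts are therefore no measure of chance alone. Among divisions for ethanol that part all 3 same-numbered pairs, the others gave 14, 19 and 14 lists, and for acetate against ethanol 4, 3 and 4. Over 100 divisions of the 9 libraries into 3 groups, 1 gave as many genes as the 671 of the true one, which was the true one itself. The highest other gave 160. The true division was always among the 100, so the smallest share possible was 1 of 100. A chance division was thus unlikely but not excluded. Over the 36 divisions with 1 library of each number in every group, 1 gave as many, the true one, and the highest other gave 126. In both sets the highest other division kept the 3 ethanol libraries together, so these counts do not speak for acetate against control alone. The divisions do not show that the replicates were separate cultures.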
